A study of Mus musculus with 2 samples.

How the data were processed

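Total RNA of cultured mouse embryonic fibroblasts, 1 Lmna+/+ and 1 Lmna-/- sample, was labelled and hybridised to Illumina bead arrays, on which each probe is carried by many beads. The genotype of each sample was taken from the labels, and each column of the tables was tied to a sample through its name. Per the labels' protocols, cells grew in high-glucose DMEM with 10% serum, RNA was purified with an RNeasy kit and amplified with an Illumina TotalPrep kit.

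The deposited intensity values are the mean bead intensity of each probe on each array, linear and, from the values, neither background-subtracted nor normalized between arrays, with medians of 86.3 for Lmna+/+ and 88.4 for Lmna-/-. Beside them stand, per the file headers, the standard error of the bead intensities, the number of beads and a detection p-value of each probe. The headers do not say how the detection p-value was computed, and it was taken here as measured against negative control beads. The scanner software and its version were not given in the sources used here. A second deposited table holds intensity values processed by the authors. Set against the first, they keep the rank order of probes within each array (Spearman rho of 1.00 on both arrays), share 1 distribution on both arrays, with a median of 4.69 and a minimum of 1.06, and are linear. The authors' background and normalization steps behind this table are known from the values alone, and it served as an alternative source.

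Intensities were corrected for background and normalized with the neqc method of limma 3.58.1 in R 4.3.3: a normal-exponential background model fitted through the detection p-values, an offset of 16, quantile normalization between the 2 arrays and log2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest. Probes were named through their Entrez gene ID (29168 probes) or RefSeq accession (1145) in the RefSeq table of the assembly GRCm38.p6, used for names and gene order only, and 14968 kept the symbol of the array's own annotation. A gene was represented by its probe with the highest mean signal over both arrays, and counted as detected where the detection p-value of that probe was under 0.01. Of 3403 genes with 2 or more detected probes, 169 differed at least 2-fold by the brightest, and 11 of these had another detected probe that differed the other way. Where no probe of a gene was detected on 1 array, the fold was given as a bound, from the signal on the bright array against the higher of the lowest signal of any detected probe on the dim array and the gene's own signal there. Counts of genes, counts of list members and list medians used the difference itself and not the bound. Folds are on the offset scale, which understates the change of dim genes.

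All differences are Lmna-/- minus Lmna+/+ on the log2 scale. With 1 array per genotype no test between samples was possible and no p-value was computed; the number of arrays limits the precision. The bead standard error of a difference was propagated from the bead errors of both arrays, with a median of 0.18 over detected genes. Before the data were examined, 27 gene lists, 10 lists of cell type markers, the alternatives and the rule for named genes were fixed. The rule named Lmna, the 15 genes with the largest and the 15 with the smallest difference among genes detected on both arrays and over 3 bead standard errors, the 8 genes brightest over the detection floor in each direction among genes detected on 1 array and not on the other (a detection p-value of 0.05 or more for every probe), and up to 4 detected members with the largest difference in each list. Clone and predicted symbols were counted but not named. For each list the median difference of detected members was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. A list lay outside the random lists where its percentile was under 2.5 or over 97.5 with at least 5 detected members. This describes these 2 arrays and is no test between genotypes, and it treats genes as independent.

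The steps were tested on simulated data: a pair of arrays drawn from the Lmna+/+ array and its bead errors, with 200 genes changed by known folds among 11645 detected genes. Of 100 genes changed 3-fold or 5-fold, 99 were called at 2-fold in the right direction. Of 50 changed exactly 2-fold, 9 were called, and of 50 changed 1.5-fold, 0. Of 11405 unchanged genes, 2 were called. A planted list of 40 genes raised 1.4-fold had a percentile of 100 among random lists, and 5 of 200 lists of unchanged genes lay outside the central 95%. The changed and planted genes were drawn from genes well above the detection floor on the Lmna+/+ array, so changes of dimmer genes were not tried. Both simulated arrays came from the same array, so variation between cultures and correlation among genes were not simulated.

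The alternatives were no background correction, an offset of 50, median scaling or cyclic loess in place of quantile normalization, the authors' processed values, other detection filters, the mean of detected probes, fold thresholds of 1.5 and 3, and a limit of 3 bead standard errors. Terms of the array's own gene ontology annotation, medians of chromosomes, list medians with members at their bounds, and list medians without genes of chromosomes 2, 12 and 15 were added after the data were seen.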

Results

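RNA from mouse embryonic fibroblast cultures of 2 genotypes was measured on Illumina bead arrays, 1 array for Lmna+/+ cells and 1 for Lmna-/- cells. Mouse embryonic fibroblasts are the mesenchymal cells that grow out of dissociated embryos, and Lmna encodes the A-type lamins, filament proteins of the nuclear lamina. The labels named no treatment. Each array reported 45281 probes. Of these, 15034 were detected, at a detection p-value under 0.01, on the Lmna+/+ array and 15534 on the Lmna-/- array. The median probe was read from 43 beads on either array, and the median detected probe had a bead standard error of 8.92% of its background-corrected signal on the Lmna+/+ array and 8.59% on the Lmna-/- array. After probes were joined to 30947 genes, 11764 genes were detected on at least 1 array and 10093 on both. There were no biological replicates, so no difference between the arrays has a replicate check, and a difference between the cultures cannot be separated from the genotype. The errors given as ± are bead standard errors, which cover the measurement on the array and not the variation between cultures.

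The signal of Lmna itself was lower on the Lmna-/- array at every probe, but not lost at all of them. The array carried 6 Lmna probes, and all of them were detected on the Lmna+/+ array. On the Lmna-/- array 5 of the 6 were not detected. The brightest of those 5, the fifth of the 6 probes in 5′ to 3′ order, had an intensity of 627 ± 27.1 in Lmna+/+ and 92.2 ± 3.33 in Lmna-/-. At this probe Lmna was at least 21.2-fold lower in Lmna-/-. The bounds for the other undetected probes lay between 1.87-fold and 12.6-fold, the smallest at the probe that was dimmest on the Lmna+/+ array.

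The remaining probe, the one nearest the 5′ end of the gene, was still detected in Lmna-/-. It read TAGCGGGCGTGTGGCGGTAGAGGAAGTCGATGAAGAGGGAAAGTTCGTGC and lay on chromosome 3 from 88288559 to 88288608 in the coordinates of the array's annotation, whose genome build was not given in the sources used here. Its intensity was 402 ± 24.3 in Lmna+/+ and 166 ± 9.23 in Lmna-/-, a log2 difference of -1.89 ± 0.20 or 3.71-fold. The probe kept 25.4% ± 3.49 of its Lmna+/+ signal over background. The 5 probes downstream of it lay between 88286454 and 88288542 on the same chromosome. Lmna sequence outside the stretch from 88286454 to 88288608 was not sampled by any probe. The labels did not name the allele, so which of the probes lie in deleted sequence is not known here.

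**Figure D1:**
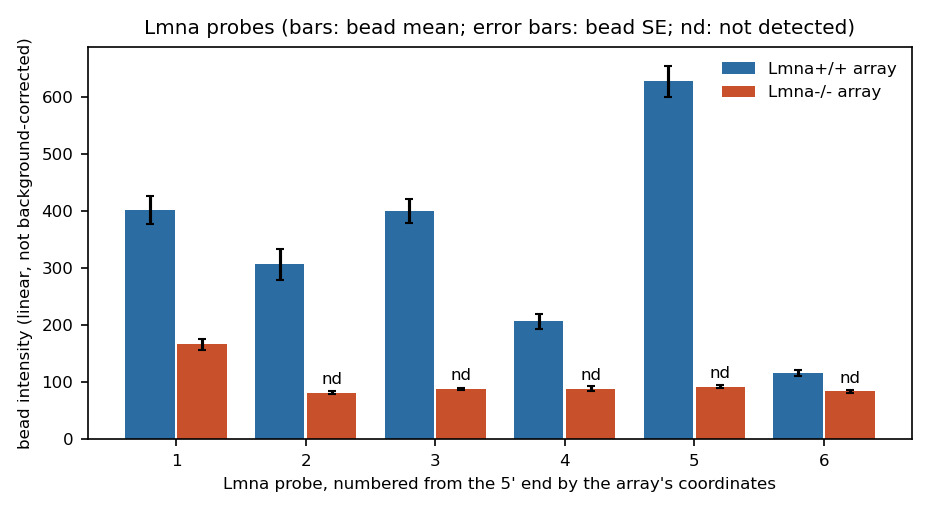
Bead intensity (linear scale, background not subtracted) of the 6 Lmna probes on the Lmna+/+ and Lmna-/- arrays, numbered from the 5′ end, with bead standard errors. Probe 1 remained detected on the Lmna-/- array at 166, and probes 2 to 6 were not detected there.

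The comparison of Lmna-/- with Lmna+/+ fibroblasts asks which transcripts differ between cultures labelled with these genotypes. Lamin protein was not measured. Of the 11764 detected genes, 399 were at least 2-fold higher and 218 at least 2-fold lower on the Lmna-/- array, and 11147 (94.8%) differed by less. These counts use the difference itself, also for genes not detected on 1 array, whose bound can be under 2-fold. Among genes detected on both arrays, 316 were at least 2-fold higher and 138 at least 2-fold lower. At least 4-fold differences were found for 44 genes in the higher and 38 in the lower direction. The share of higher genes among the at least 2-fold differences was 64.7%, and it was 75.6% (520 higher and 168 lower) when the arrays were scaled to equal medians instead of equal quantiles. The counts depended on the scale, with 127 higher and 60 lower without background correction and 1185 and 784 from the authors' processed values. Across detected genes the 2 arrays correlated with a Pearson r of 0.967, a value across genes, which are not independent replicates.

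The tetraspanin Tspan8 (log2 difference 4.46 ± 0.26) was 22.0-fold higher in Lmna-/-, the membrane glycoprotein gene Gpm6a (log2 difference 4.23 ± 0.22) 18.7-fold, Vat1l 18.4-fold (4.20 ± 0.34) and Flrt3, a fibronectin-leucine-rich adhesion protein, 12.7-fold (3.66 ± 0.33). The bright transcript of the cold-shock protein Ybx3 was 8.09-fold higher (3.02 ± 0.08), although 4 detected probes of this gene ranged from -0.80 to 3.02. Differences of 7.11-fold to 7.76-fold were measured for Cysltr1, the anchoring protein gene Akap12, the Wnt enhancer Rspo3, the TAM receptor ligand Gas6, Rtn1, Arhgap44 and Ermp1. The LIM protein gene Fhl1 was 6.71-fold, Tagln, an actin-binding protein of smooth muscle, 5.66-fold and Zbtb8b 5.64-fold higher. These folds are those of the brightest probe, and the least different detected probe had a log2 difference of 1.26 for Rspo3, 0.69 for Fhl1, 0.63 for Ermp1 and 0.48 for Rtn1. Gpm6a and Akap12 each had 1 detected probe of 3, and Tagln 1 of 2. Several genes were detected in Lmna-/- and not above background in Lmna+/+: Parm1 was at least 8.70-fold higher, Fam184a 8.35-fold, the imprinted gene Peg3 5.67-fold and the complement regulator Cd55 5.52-fold. Myl7, Pknox2, Bex4 and the oestrogen receptor gene Esr1 had bounds from 2.69-fold to 2.82-fold. Pknox2 had 1 detected probe of 5, and Esr1 1 of 4. Second detected probes differed by less, with log2 differences of 1.12 for Parm1, 2.13 for Fam184a, 0.76 for Peg3 and 1.05 for Bex4.

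The largest difference among genes detected on both arrays was that of Mgp (log2 difference -5.10 ± 0.23), matrix Gla protein, an inhibitor of calcification, at 34.3-fold lower in Lmna-/-. Rerg was 11.5-fold lower (-3.53 ± 0.47), the homeodomain-only gene Hopx 9.65-fold (-3.27 ± 0.21) and Spp1, which encodes osteopontin, 6.91-fold (-2.79 ± 0.10). The proliferin genes Prl2c3, Prl2c4 and Prl2c2 were 8.19-fold, 6.98-fold and 6.56-fold lower, but they are near-identical copies whose probes can share signal, and the same holds for Serpina3n (6.15-fold lower). Chst1 and Prr9 were 6.67-fold and 5.89-fold lower. Among transcription factors, Sox9, a regulator of cartilage formation, was 5.01-fold, the mesenchymal homeobox gene Prrx1 4.25-fold and Foxq1 4.10-fold lower, with other detected probes of Sox9 and Prrx1 differing by as little as -0.66 and -0.61. The water channel gene Aqp5 was 4.03-fold lower, and Plpp3 4.80-fold lower at its brightest probe and 0.42 (log2) higher at its other detected probe. Genes detected in Lmna+/+ and not above background in Lmna-/- included the fibroblast growth factor gene Fgf7, at least 22.7-fold lower, the water channel Aqp1 (19.1-fold), the BMP antagonist Grem1 (16.4-fold) and the lipocalin Lcn2 (16.2-fold). Col6a3, Aldh3a1 and Serpine2 were at least 9.96-fold, 9.38-fold and 6.56-fold lower. Col6a3 had 1 detected probe of 3, and Serpine2 and Hopx each 1 of 2. Of the 3 Aqp1 probes the least different had a log2 difference of -2.22.

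**Figure D2:**
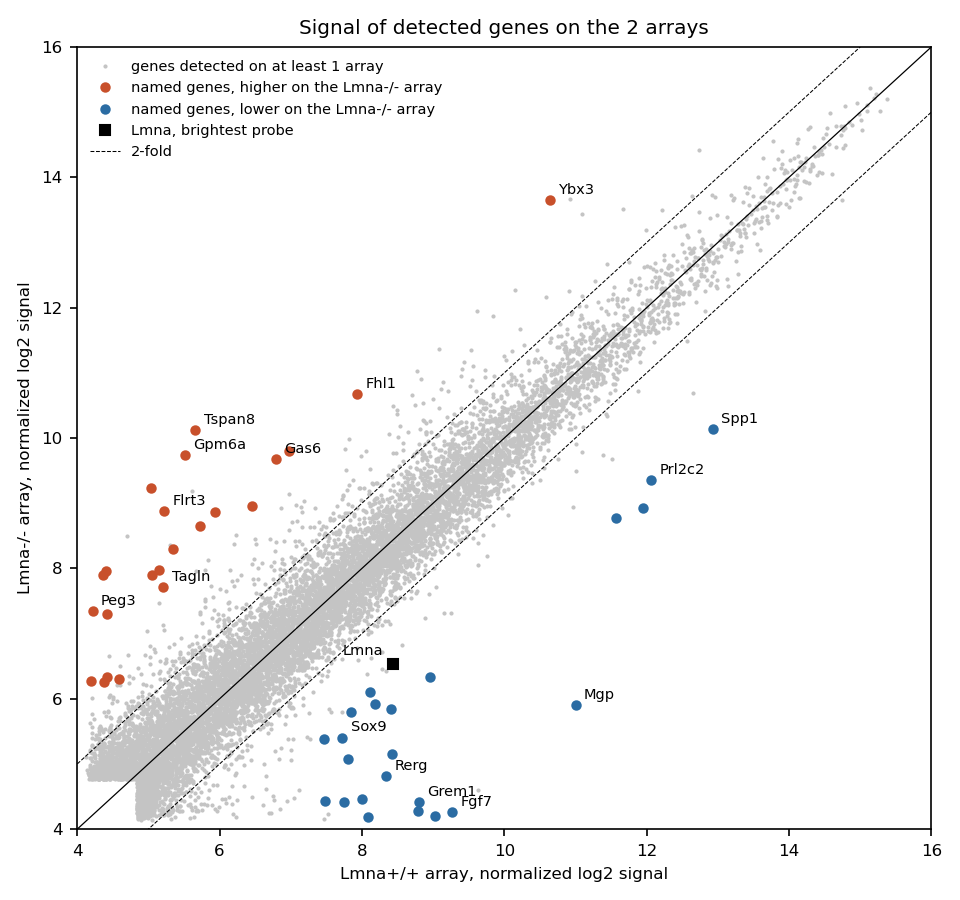
Normalized log2 signal of each gene detected on at least 1 array, Lmna+/+ on the horizontal and Lmna-/- on the vertical axis, with the named genes in colour, the Lmna probe that was brightest over both arrays as a square, the line of equality and dashed lines at 2-fold. Mgp lies farthest below the line among genes detected on both arrays (-5.10), and Tspan8 farthest above it (4.46).

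Extracellular matrix, contractile and growth factor pathway genes were mostly higher in Lmna-/-. Of 37 detected collagens and other matrix proteins, 16 were at least 1.5-fold higher and 7 at least 1.5-fold lower, with a median log2 difference of 0.55, above the -0.18 to 0.14 that held the central 95% of random gene lists of equal size and signal. The type IV collagen gene Col4a2 (4.87-fold) was highest in this group, while Mgp, Col6a3 and Spp1 went the other way. Matrix proteases and their inhibitors had a median of 0.35 (random lists -0.23 to 0.22), with 7 of 23 higher and 3 lower by 1.5-fold. Mmp10 was 3.20-fold higher, whereas Adam12 was 2.25-fold lower and the bone protease gene Ctsk at least 3.23-fold lower. The contractile cytoskeleton and MRTF-SRF targets had a median of 0.46 (random lists -0.21 to 0.19), with 11 of 25 higher and 1 lower. Smooth muscle actin, Acta2, was 3.20-fold higher (1.68 ± 0.07) and filamin A, Flna, 2.51-fold (1.33 ± 0.15), beside Fhl1 and Tagln.

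The YAP-TAZ targets, transcripts driven by the mechanosensitive co-activators YAP and TAZ, had a median of 0.67 (random lists -0.26 to 0.25). Of their 16 detected members 9 were at least 1.5-fold higher and 0 lower, led by Tgfb2 (3.04-fold), Crim1 (2.94-fold), Ccn1 (2.45-fold) and Ccn2 (2.28-fold). TGF-beta and BMP pathway genes had a median of 0.65 (random lists -0.22 to 0.22), 14 of 24 being higher and 3 lower. Tgfb3 was 2.75-fold and the activin antagonist Fst 2.17-fold higher, and Grem1 was lower as given above. Wnt pathway genes had a median of 0.59 (random lists -0.26 to 0.33), with 11 of 21 higher and 2 lower. Wnt5a was 3.88-fold and Wnt4 3.57-fold higher beside Rspo3, with detected Wnt5a probes from 0.71 to 1.95, whereas Ccn5 was at least 4.85-fold lower. Over the 11 alternative settings these medians stayed above the random lists but changed in size, ranging from 0.39 to 0.87 for YAP-TAZ targets, 0.20 to 0.38 for matrix proteases and their inhibitors and 0.30 to 0.54 for contractile genes. The Wnt median was 0.24 without background correction, 0.29 without the detection filter and 1.003 from the authors' processed values.

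**Figure D3:**
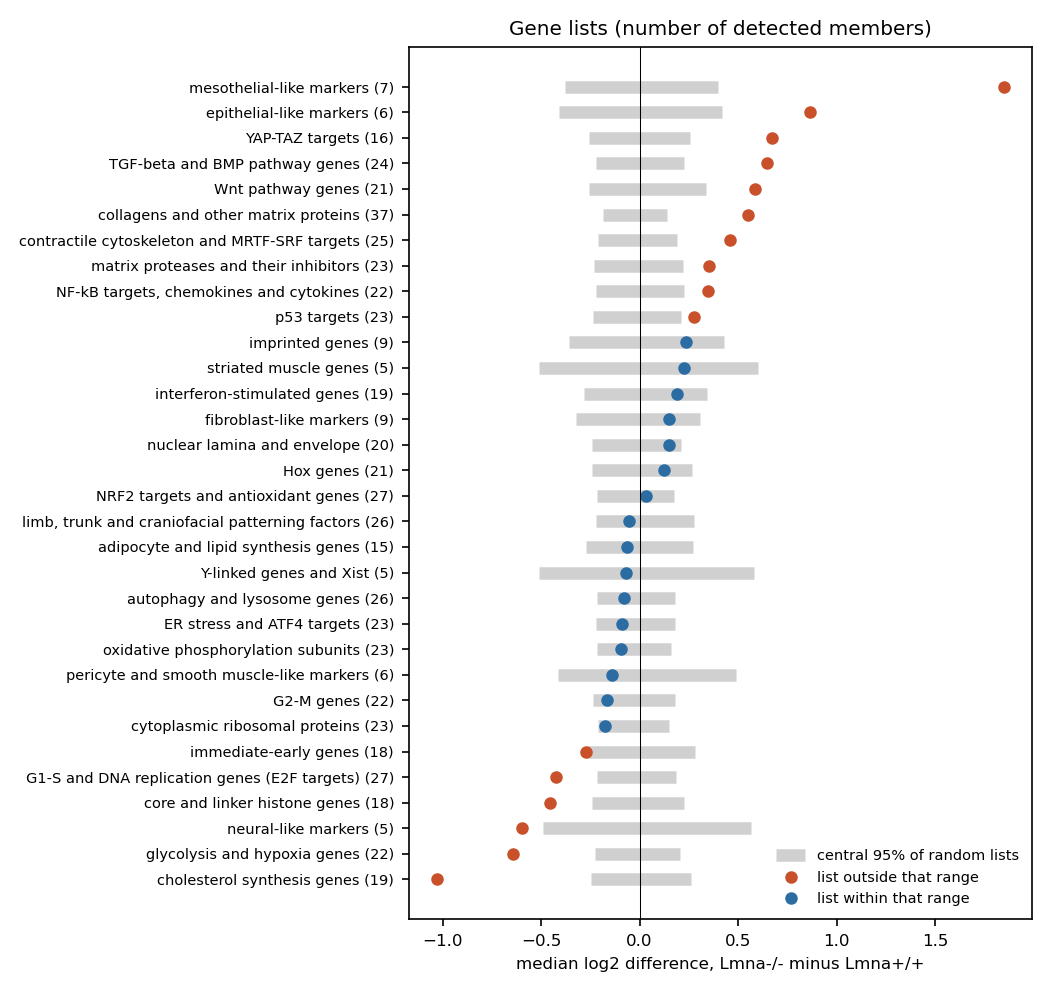
Median log2 difference (Lmna-/- minus Lmna+/+) of every gene list and marker list with at least 5 detected members, with the number of detected members in parentheses; grey bars span the central 95% of medians of 10000 random lists matched on size and signal. Mesothelial-like markers (1.85) lie at the top and cholesterol synthesis genes (-1.03) at the bottom.

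Cholesterol synthesis, glycolysis and DNA replication genes were mostly lower in Lmna-/-. The cholesterol synthesis genes had the lowest median of all lists, -1.03 (random lists -0.25 to 0.26), and 12 of 19 detected members were at least 1.5-fold lower and 0 higher. Insig1, a sterol-responsive regulator, was 3.76-fold (-1.91 ± 0.18), Fdps 2.85-fold (-1.51 ± 0.09, a second probe -0.36) and Nsdhl 2.79-fold (-1.48 ± 0.19) lower, and Cyp51 had a log2 difference of -1.58 ± 0.10. The transcription factor gene Srebf2, chosen after its value was seen, differed by -0.08 ± 0.11 at its brightest probe and by -1.19 at its other detected probe. Glycolysis and hypoxia genes had a median of -0.64 (random lists -0.23 to 0.20), with 12 of 22 lower and 1 higher. Pdk1, which encodes a kinase that restrains pyruvate oxidation, was 2.83-fold, Ankrd37 2.56-fold and the oxygen sensor gene Egln1 2.14-fold lower, with the 3 detected Egln1 probes ranging from -1.10 to 0.20, and Adm was at least 1.66-fold lower.

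Of the G1-S and DNA replication genes, 8 of 27 were at least 1.5-fold lower and 0 higher, with a median of -0.43 (random lists -0.21 to 0.18). Rfc3, Ccne2, Rrm2 and Tk1 were 1.82-fold, 1.79-fold, 1.78-fold and 1.71-fold lower. G2-M genes had a median of -0.16, within the range of random lists (-0.24 to 0.18), and Cdc20 (1.74-fold lower) was the single member of 22 past 1.5-fold. The list of core and linker histone genes had a median of -0.46 (random lists -0.24 to 0.22), with 6 of 18 lower and 1 higher. Its largest differences were mostly those of other chromatin proteins on the list, Hmgb2 (2.25-fold lower), the heterochromatin protein gene Cbx5 (1.89-fold) and Hmga1 (1.79-fold, with a second probe 0.39 higher), beside the histone gene H2bc21 (2.05-fold). Histone genes have near-identical copies, so the probe of a single histone gene is uncertain. Without background correction the medians were closer to 0, -0.63 for cholesterol synthesis and -0.41 for glycolysis and hypoxia genes, and the histone list reached -0.29 among the alternatives.

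**Figure D4:**
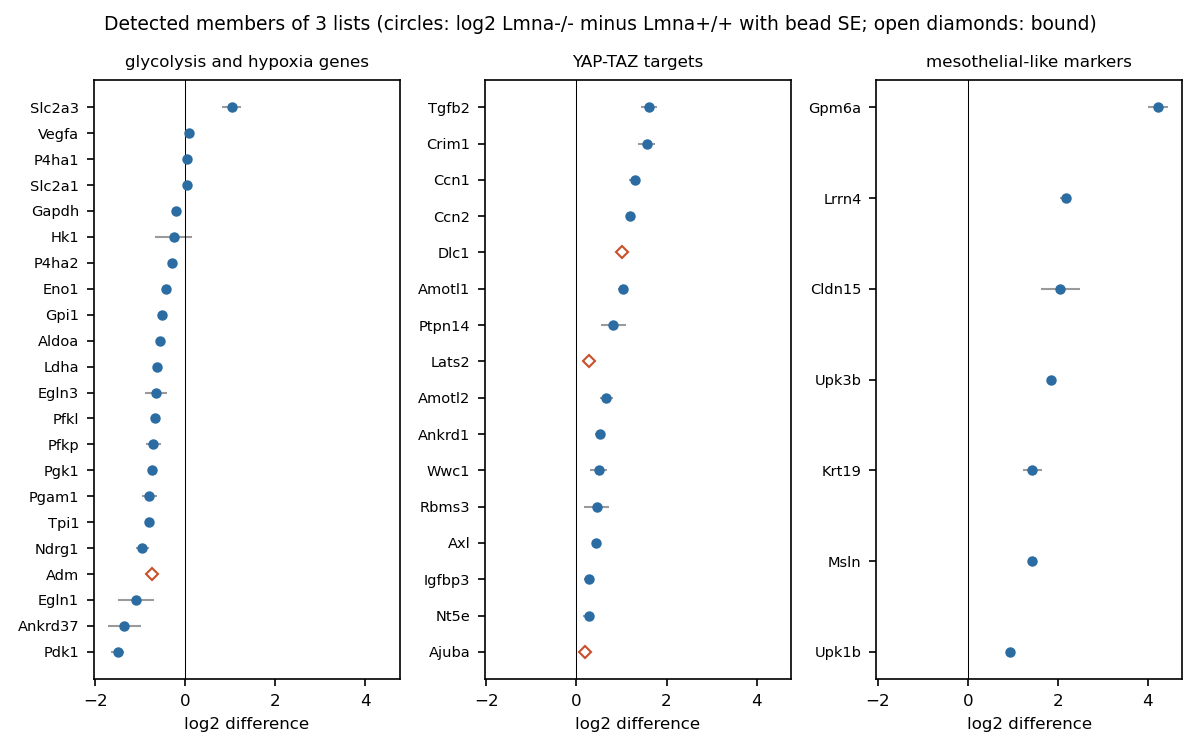
Log2 difference (Lmna-/- minus Lmna+/+) of each detected member of 3 lists, with bead standard errors; open diamonds mark bounds of genes not above background on 1 array. Glycolysis and hypoxia genes reach -1.50 (Pdk1), YAP-TAZ targets 1.61 (Tgfb2) and mesothelial-like markers 4.23 (Gpm6a).

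Inflammatory genes went both ways. The NF-kB targets, chemokines and cytokines had a median of 0.35 (random lists -0.22 to 0.22), with 8 of 22 at least 1.5-fold higher and 6 lower. The acute phase gene Saa3 was 5.11-fold higher, while the chemokine Cxcl12 was 3.90-fold lower, Lcn2 at least 16.2-fold and the IL-33 receptor gene Il1rl1 at least 29.1-fold lower. Without the detection filter this list had a median of 0.094 and no longer lay outside the random lists, and with the authors' processed values it had 0.58. The p53 targets had a median of 0.27 (random lists -0.24 to 0.21), with 6 of 23 higher and 0 lower, among them Plk3 (1.72-fold), Zmat3 (1.70-fold), Mdm2 (1.70-fold) and Trp53inp1 (1.68-fold). Immediate-early genes lay at the edge of the random range, with a median of -0.27 (random lists -0.27 to 0.28), and fell inside it under 5 of the 11 alternative settings. Klf4, Myc and Btg1 were 2.56-fold, 2.29-fold and 2.11-fold lower, and Dusp1 was 2.64-fold higher.

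The other 14 lists lay within the range of random lists. The nuclear lamina and envelope genes had a median of 0.15 (random lists -0.24 to 0.21), with 2 of 20 higher and 2 lower by 1.5-fold. The protease gene Zmpste24, whose product matures prelamin A, was 1.80-fold higher at its brightest probe (detected probes from -0.06 to 0.85) and Tor1aip2 1.74-fold higher, and the farnesyltransferase subunit gene Fntb and Syne3 were 1.57-fold and 1.56-fold lower. Chosen after their values were seen, the B-type lamin genes Lmnb1 and Lmnb2 differed by -0.09 ± 0.10 and -0.02 ± 0.13 at their brightest probes, with either sign across normalizations, a second Lmnb1 probe differed by -0.54, and the emerin gene Emd by -0.55 ± 0.08. Medians were 0.19 for interferon-stimulated genes, where Gbp2 was 2.69-fold higher, -0.06 for adipocyte and lipid synthesis genes, where the lipase gene Lpl was 5.06-fold higher, and 0.03 for NRF2 targets, where Gsta4 was 2.55-fold higher and Nqo1 2.23-fold lower. Patterning factors of limb, trunk and face had a median of -0.05, and their largest differences were the lower signals of Prrx1, Twist2 (3.14-fold) and Tcf21 (2.24-fold). Hox genes had a median of 0.13, led by Hoxd4 (2.12-fold higher) and Hoxa5 (2.08-fold higher). Imprinted genes had a median of 0.23, with Peg3 higher and Ndn at least 3.96-fold lower. The remaining medians were 0.22 for striated muscle genes, -0.09 for ER stress and ATF4 targets, -0.09 for oxidative phosphorylation subunits, -0.08 for autophagy and lysosome genes and -0.18 for cytoplasmic ribosomal proteins. In the list of Y-linked genes and Xist, with a median of -0.07, the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were detected on both arrays, and Xist on the Lmna+/+ array alone, at least 1.35-fold lower in Lmna-/-.

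Markers of other cell types were measured to describe what the cultures held. The 7 detected mesothelial-like markers, genes of the cells that line body cavities, were all at least 1.5-fold higher in Lmna-/-, with a median of 1.85 (random lists -0.38 to 0.40). Gpm6a was 18.7-fold, Lrrn4 4.51-fold, Cldn15 4.16-fold and Upk3b 3.60-fold higher, with detected Cldn15 probes from 0.71 to 2.06. Upk3b was among the bright genes of both arrays, with a log2 signal of 11.67 in Lmna+/+ and 13.52 in Lmna-/-. Epithelial-like markers had a median of 0.86 over 6 detected members of 16 (random lists -0.41 to 0.42), with Krt14 3.50-fold and Krt19, which is also on the mesothelial-like list, 2.71-fold higher. With members admitted at the looser detection threshold the epithelial-like median was 0.25, within the random range. These higher marker signals were measured in the same Lmna-/- culture as the higher matrix, contractile, YAP-TAZ, Wnt and TGF-beta lists. Fibroblast-like markers had a median of 0.15 over 9 detected members of 12, within the random range (-0.32 to 0.31), with Col1a1 1.76-fold higher and Vim 1.47-fold lower. Thy1, Fap and Lum were detected on neither array.

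Other marker lists had few detected members. Neural-like markers had a median of -0.60 over 5 members (random lists -0.49 to 0.56), with Ncam1 2.31-fold higher (detected probes from 0.55 to 1.21) and Gap43 at least 2.09-fold lower, and the sign turned with the detection filter. Pericyte and smooth muscle-like markers had a median of -0.14 over 6 members, Acta2 being the single one higher by 1.5-fold. Macrophage and blood-like markers had a median of -0.42 over 4 members, with Cd68 2.32-fold lower. Endothelial-like markers had a median of -0.11 over 3 members, chondrocyte and osteoblast-like markers 0.55 over 3, and pluripotent-like markers -0.44 over 2. No adipocyte-like marker of the 6 on the array was detected.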

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

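The bounds of list members and the lists without genes of chromosomes 2, 12 and 15 were chosen after the data were seen. No paired analysis was possible because each genotype has 1 array. Of 190 named genes, 104 differed at least 2-fold, and 0 of their 624 values under 6 alternatives had the other sign. This is no independent check, since the 104 were taken by their difference and the alternatives use the same intensities. Of 516 values of the 86 genes under 2-fold, 10 had the other sign, from 9 genes, Eif2s3y the farthest at -0.16. In all, 137 of 1140 values moved beyond the bead error. Detection filters do not enter the value of a single gene. The counts depended on the scale. Genes at least 2-fold higher in the Lmna-/- array numbered 127 with no background correction, 198 with offset 50, 1185 with the authors' processed values, 1468 at the 1.5-fold and 106 at the 3-fold threshold. Genes at least 2-fold lower numbered 60, 96, 784, 1109 and 73 under the same settings, 138 among genes detected on both arrays and 144 among those over 3 bead standard errors. A larger offset, or background left in, shrinks log ratios of dim genes by construction, and the filters leave fewer genes. The authors' values were taken to log2 without an offset, which widens log ratios of dim genes by construction. Whether other steps behind those values add to their larger counts was not tested. All 399 higher and 218 lower genes were among those of the authors' values, which come from the same 2 arrays and are no independent check.

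Of 297 medians of the 27 gene lists under the alternatives, 289 moved by less than the spread of random lists, and 0 of those of the 13 lists outside the random range turned. With no background correction the median was 0.39 for YAP-TAZ targets, 0.24 for Wnt pathway genes, -0.63 for cholesterol synthesis genes and -0.41 for glycolysis and hypoxia genes. With the authors' values it was 0.58 for NF-kB targets, chemokines and cytokines and 1.003 for Wnt pathway genes, and with no detection filter 0.094 and 0.29. The neural-like median turned to 0.90 among genes detected on both arrays, where 2 members are left, and to 0.028 without a filter, where undetected members enter. Lmna was -1.28 with no background correction and -3.09 as the mean of its detected probes, which adds the 5 lost probes. The cause of the list shifts was not tested. Of the 13 gene lists outside the random range, 11 stayed outside it under every alternative. Immediate-early genes lay inside it under 5 of 11 settings, where the median reached -0.13, and the NF-kB list under 1. Of the lists within it, interferon-stimulated genes lay outside with members at their bounds, and chondrocyte and osteoblast-like markers with no detection filter. Among genes detected on both arrays the pericyte and smooth muscle-like median was 0.90 over 2 members and the chondrocyte and osteoblast-like median -0.66 over 2, too few for a call. Signal over background limits the 19183 genes detected on neither array, for which no difference can be read.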

Other observations

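The tests of the Lmna probes, of surface epithelium and of chromosome parts were chosen after the values were seen, as were the gene ontology terms and the genes named in this part; the second mesothelial list, the GC test and the test without strongly changed genes had their predictions written before their results were seen, and the requirement that the second mesothelial median lie below the first list's by more than the spread of random lists was added after.

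Other gene groups also differed between the arrays. Among 479 terms of the array's ontology annotation with 10 to 300 detected genes, 70 lay above and 57 below the central 95% of random lists, where chance would put 2.5% of independent terms on each side; the terms overlap. Cell adhesion genes had a median log2 difference of 0.37 over 137 genes (random lists -0.10 to 0.09). Basement membrane genes had a median of 0.54 over 25 genes (random lists -0.23 to 0.22), and the laminin genes Lama5 and Lamb2 were 4.46-fold and 3.35-fold higher in Lmna-/- beside Col4a1, 4.37-fold higher. MHC class I genes, which present antigen at the cell surface, had a median of 0.68 over 13 genes (random lists -0.30 to 0.36), 9 of them at least 1.5-fold higher and 0 lower. H2-K1 was 2.23-fold, H2-D1 1.84-fold and H2-T23 1.62-fold higher, values that remain uncertain because these genes are close copies and differ between mouse strains.

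Nucleosome assembly genes had a median of -0.45 over 47 genes (random lists -0.17 to 0.14), with 15 at least 1.5-fold lower and 1 higher, most of them histone genes with shared sequence. Genes of mRNA splicing had a median of -0.26 over 85 genes (random lists -0.13 to 0.09), 13 of them at least 1.5-fold lower and 1 higher. The splicing regulators Hnrnpa1, Tra2b and Srsf10 were 2.47-fold, 1.72-fold and 1.69-fold lower at their brightest probes, with the 4 detected Srsf10 probes ranging from -0.79 to 0.05.

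The first pattern is the Lmna signal left on the Lmna-/- array. The most 5′ probe kept 25.4% ± 3.49 of its Lmna+/+ signal over background, whereas the 5 probes downstream kept 1.46% ± 0.426 as a mean weighted by bead error, which argues against RNA of Lmna+/+ cells in the Lmna-/- sample as its source. A first form of this test took the largest share kept by any of the 5, 9.13% ± 8.10 at the dimmest, and decided nothing; the weighted mean replaced it after that result was seen. A transcript that ends or is cut downstream of the first probe may leave this signal, but that 0 of the downstream probes were detected in Lmna-/- is the pattern itself and decides nothing; a known Lmna null allele of mice lacks 3′ exons and keeps a shortened transcript, but the labels do not say which allele these cells carry. Cross-hybridisation of the first probe was not tested, as no genome was used here.

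The second pattern is the higher signal of the 7 mesothelial-like markers (median 1.85). An equal gain of mesothelial-type cells should raise other mesothelial transcripts by a like amount. However, a second list of 14 markers, of which 7 were detected, had a median of 0.32. That median lay inside the -0.39 to 0.47 of random lists and below the first list by more than their spread. By the difference itself, 2 members were at least 1.5-fold higher, Podxl (0.90 ± 0.29) and the dim Rspo1, and 0 lower. Rspo1 was not detected on the Lmna+/+ array, and its bound was 1.08-fold. The brightest members of the second list were Pdpn (0.21 ± 0.08) and Slpi (-0.32 ± 0.07), both of which fibroblasts or other epithelia may also make. The mesothelial regulator Bnc1 differed by 0.05 ± 0.16. The member at the median, Muc1 (0.32 ± 0.80), was near background and not detected on the Lmna+/+ array. With so few specific and well-detected members, the second list cannot exclude a gain of mesothelial-type cells. Surface epithelium cells would bring Krt5, Cdh1 and Epcam, and 0 of these 3 were detected on the Lmna-/- array although Krt14 was bright. These 3 were chosen after their values were seen, and the 6 detected epithelial-like markers were all higher in Lmna-/-. Their absence therefore cannot exclude surface epithelium cells. A gain of mesothelial-type cells stays open. A change of part of the mesothelial programme with the Lmna genotype, or between 2 separately grown cultures, also stays open, since the design confounds them.

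The third pattern is a shift of whole chromosomes. Genes of chromosome 2 had a median log2 difference of 0.19 over 764 genes, with 68.8% of them higher in Lmna-/-, and those of chromosomes 12 and 15 had medians of -0.20 over 308 and -0.20 over 398 genes, with 36.7% and 34.9% higher, against 49.9% of all detected genes; these 3 were picked for a median beyond 0.15, and 15 of the 20 chromosomes lay outside the central 95% of random lists. Probe GC content and signal as the whole source were argued against, since the smallest of the 3 sizes was still 0.16 once their trend was removed. Leaving out genes changed 1.5-fold left a smallest size of 0.11, but this removes genes by the change itself and a median over so many genes cannot rest on a few, so it decides nothing. A different copy number of these chromosomes in part of the cells of 1 culture could give such shifts and stays open beside genotype and culture history, since no DNA was measured and the 6 of 6 chromosome parts outside the random range come from chromosomes picked for their shift. Without the genes of these chromosomes 12 of the 13 gene lists outside the random range stayed outside it, and immediate-early genes, at a percentile of 2.60, did not; the cholesterol synthesis median was -1.03 and that of the YAP-TAZ targets 0.67.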
